A study of Homo sapiens with 18 samples.

How the data were processed

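The series holds 18 small RNA libraries of DKO-1 cells: control, METTL3 shRNA and ALKBH5 shRNA lines, each with 3 libraries of cellular RNA and 3 of RNA from EVs. Per the labels' protocols, stable lines expressed the shRNAs, cells were grown in DMEM with 10% fetal bovine serum, EVs were purified from the medium after 48 hours, RNA was taken with Trizol, and libraries were made with a small RNA kit, size-selected on a Pippin Prep and sequenced on a NextSeq500. Per the submitters' processing notes, cutadapt, Bowtie and DESeq2 were used with the hg19 genome; their versions, the annotation and how reads with several locations were shared out are not stated.

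The deposited table holds expected counts per feature and library, whose fractional values show that the authors divided reads that match several features, by a rule they do not state. Between 11.4% and 19.5% of the values of a library are not whole numbers. The table has 10991 features with hg19 coordinates and an RNA class. The classes as deposited are miRNA, tRNA, rRNA, Y RNA, snoRNA, snRNA, mitochondrial tRNA, miscellaneous RNA and lincRNA, and 283 features merge several names, such as tRNA genes of identical sequence. Whole counts had been assumed when the tests were planned; the values were rounded to whole numbers before every count test, and the planned tests were kept. Class assignment, and features that share reads with near-identical copies such as U1, U2, Y RNA and miRNA paralogs, rest on the authors' counting. RMRP and SNORD3D are given as lincRNA in the table.

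Groups and comparisons followed the labels. Knockdown lines were compared with control and with each other within cells and within EVs, EVs were compared with cells within each line, and the difference of EV to cell ratios between each knockdown line and control was tested, which makes 11 comparisons. Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM scaling over all features, glmQLFit and glmQLFTest, two-sided), with the 9 libraries of a compartment in the fit for line comparisons and all 18 for EV comparisons. This left 1206 features in cells, 1697 in EVs and 1841 over all libraries, which held at least 99.91%, 99.86% and 99.86% of the counts of each library. Features with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are log2 with a standard error taken from the fold change and its F statistic, and levels are CPM on TMM-scaled library sizes of the fit that gave the fold change. Shares of RNA classes were compared by a two-sided exact permutation test, whose smallest p with 3 libraries against 3 is 0.1. Per library, the limit set by a count of 0 was taken as 3 counts; PCR copies are not independent molecules, so such limits cover counting error only.

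The 19 miRNA lists were the let-7, miR-17-92, miR-200, miR-192 and miR-194, miR-15 and miR-16, miR-29, miR-30, miR-34 and miR-449a, miR-23, miR-24 and miR-27, miR-221 and miR-222-3p, miR-10 and miR-100 (with miR-99 and the miR-125 members), miR-320, miR-181, miR-148 and miR-152-3p and miR-26 families or clusters, miRNAs raised in colorectal cancer, mirtrons, blood, serum and liver miRNAs, and mesenchymal and muscle miRNAs. They were tested with camera in limma 3.58.1 on log2 CPM of miRNAs with a preset correlation of 0.01 where at least 3 members were tested, adjusted over the lists of a comparison, and again with an estimated correlation. The DRACH motif was searched in the mature sequences of the table, and 493 of 1790 miRNA features hold it. The comparisons, tests, lists, naming rule and alternatives were chosen before the data were examined. The naming rule took, per comparison, called features with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups: the 8 miRNAs that rose most and the 8 that fell most, and the 3 of each other class that rose most and fell most. It added up to 4 members of each list with the highest mean CPM, and the 10 most abundant miRNAs of control cells and control EVs. METTL3 and ALKBH5 were to be given in every library, but the table does not hold them.

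The alternatives tried were DESeq2's size factors in edgeR, DESeq2 1.42.0 itself, no filter on low counts, miRNA features alone, the replicate number as a block, leaving out each library, and another set of libraries in the fit. The pairing of replicate numbers was checked by correlating the deviations of same-numbered libraries from their group means. All 3 pairs were above 0.1 for METTL3 shRNA against control cells (0.270, 0.111 and 0.225) and for METTL3 shRNA against ALKBH5 shRNA EVs (0.201, 0.170 and 0.131), and not for the other comparisons; the pairing comes from this check, not from the labels. The fits without control EV replicate 3 for comparisons that do not use it as a group, and the motif test without the miR-10 and miR-100 family, were added after the data were seen. The count test and camera were tested on simulated data with 100 changed features at each fold size. Each feature was drawn independently of the others, so camera's error where list members vary together was not measured. For EVs against control cells, unchanged features had the same mean in both compartments, without the real shift between RNA classes. The count test recovered 60% of 2-fold and 97% of 4-fold changes for METTL3 shRNA against control cells, 29% and 86% for METTL3 shRNA against control EVs, 29% and 79% for EVs against control cells, and 1% and 52% for the METTL3 shRNA change of EVs against cells, with 4.39% to 6.45% of calls false, and camera gave a p under 0.05 to at most 3 of 100 unchanged lists. For the search of miRNA sequences inside other RNAs, 5222 transcripts of other small RNA classes in the reference were used; 18S and 28S rRNA were not among them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

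Knockdown comparisons within a compartment share their control libraries. The fold changes of the METTL3 and ALKBH5 shRNA lines against control correlated at 0.542 across 1206 features in cells, where unchanged groups against the same controls gave 0.524 on average, and at 0.487 in EVs, where they gave 0.499. The covariance was 0.122 in cells against a simulated 0.0571, and 0.103 in EVs against 0.0822. The real values came from edgeR's fold changes, and the simulated ones from differences of mean log2 CPM with a small count added. That addition shrinks differences at low counts, and simulated features were drawn independently. The gap between real and simulated covariance therefore does not show a shared change of the knockdown lines. No feature was called in both, and the 3 control libraries are too few to be split.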

Results

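Small RNA was sequenced from DKO-1 cells, a colorectal cancer line with mutant KRAS, and from the extracellular vesicles (EVs) they released into the medium. The study used 3 stable lines: a control line and lines expressing a short hairpin RNA (shRNA) against METTL3 or against ALKBH5. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) into RNA, and ALKBH5 is a demethylase that removes it. The series asks how loss of each enzyme affects the export of small RNAs into EVs. Each line gave 3 libraries of cellular RNA and 3 of EV RNA, which makes 6 groups and 18 libraries, 9 of them from cells and 9 from EVs. Cell libraries held between 2957296 and 8415464 counts (median 5763306), and EV libraries between 8897284 and 10157455 (median 9544460). A count of 0 therefore allowed a level of up to 0.356 to 1.014 CPM (counts scaled to library size) in cells and 0.295 to 0.337 CPM in EVs, limits that cover counting error only. The messenger RNAs of METTL3 and ALKBH5 are not among the features of the table, so the knockdowns could not be checked in these libraries. The labels do not say whether the replicates were separate cultures, and the p-values measure the spread between these libraries. Each knockdown is represented by 1 line, and the control is called both control and parental, so it is not stated whether it carried a hairpin.

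MicroRNAs (miRNAs), the short guides of RNA silencing, made up most of the cellular counts, while fragments of tRNA and rRNA took the larger part of the EV counts. In control cells miRNAs held 76.1% ± 2.13 (SD, n = 3) of counts, rRNA 12.5% ± 1.16, small nucleolar RNAs (snoRNAs) 4.01% ± 0.667 and tRNA 3.70% ± 0.920. In control EVs tRNA held 37.6% ± 6.30, miRNAs 29.98% ± 12.5, rRNA 20.5% ± 17.7, Y RNA 8.79% ± 0.775 and snoRNAs 0.255% ± 0.0495. In both knockdown lines the cells had a lower miRNA share and a higher rRNA share than control cells, with no overlap between libraries. The miRNA share was 69.4% ± 4.08 in METTL3 shRNA cells and 65.6% ± 3.24 in ALKBH5 shRNA cells, and the rRNA share was 16.8% ± 1.27 and 17.6% ± 2.06. ALKBH5 shRNA cells also had a snoRNA share of 6.94% ± 1.52, above that of every control and METTL3 shRNA library. Each of these differences had p = 0.1 by the two-sided exact permutation test, the smallest value that 3 libraries against 3 can give. Among EVs, the Y RNA share of the ALKBH5 shRNA line, 6.15% ± 1.17, lay below every control library (exact p = 0.1), and the miRNA, tRNA, rRNA and snoRNA shares overlapped between lines. Libraries of one EV group differed widely in rRNA: the large-subunit 28S rRNA took 37.0% of counts in control EV replicate 3 but 8.02% and 4.54% in the other control EV libraries, and 43.0% in METTL3 shRNA EV replicate 1.

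**Figure D1:**
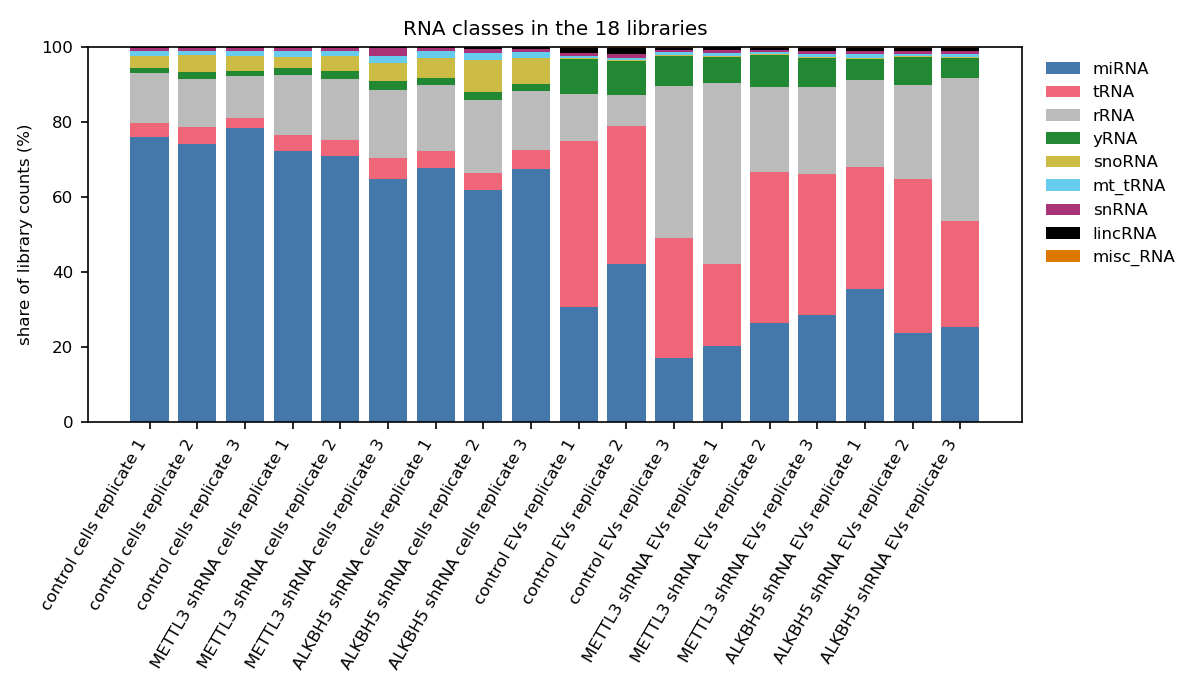
Stacked bars give the share of each library's counts, in percent, held by each RNA class in the 18 libraries, from cells (first 9 bars) and EVs (last 9 bars). MicroRNA held 61.9% to 78.3% of counts in every cell library and 17.1% to 42.1% in every EV library, while tRNA held 2.79% to 5.58% in cells and 21.9% to 44.3% in EVs.

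The most abundant miRNA of control cells was the oncogenic miR-21-5p, at 20.5% ± 0.638 of miRNA counts (mean and SD, n = 3; hg19 chromosome 17, 57918634 to 57918655), followed by miR-10a-5p at 11.9% ± 1.503 (chromosome 17, 46657266 to 46657288), miR-29a-3p at 5.01%, the epithelial miR-200b-3p at 3.87% and let-7a-5p at 3.82%. In control EVs the order changed, with miR-10a-5p at 14.3% ± 5.79, miR-21-5p at 12.3% ± 4.86, miR-29a-3p at 6.66% and miR-92a-3p, a member of the miR-17-92 oncogenic clusters, at 5.21% ± 0.967. The 10 most abundant miRNAs held 59.2% ± 1.61 of miRNA counts in control cells and 56.4% ± 1.00 in control EVs.

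The first comparison asks how loss of the m6A writer changed small RNAs inside cells. Against control cells, METTL3 shRNA cells had lower miR-100-5p and miR-125b-5p, which derive from neighbouring hairpins on chromosome 11 and belong to the conserved miR-10 and miR-100 family. miR-100-5p (122022983 to 122023004) fell by 1.81 ± 0.28 on the log2 scale (SE), from 318 ± 36.1 to 90.6 ± 13.9 CPM (SD, n = 3 per group). miR-125b-5p fell by 1.86 ± 0.30, from 134 ± 38.1 to 36.8 ± 7.38 CPM. Its mature sequence has 2 locations in the genome, and the chromosome 11 one spans 121970517 to 121970538. Both had an adjusted p of 0.0188 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The only feature that rose was RNU1-11P (ENSG00000206702; chromosome 6, 13214288 to 13214451), a copy of the U1 spliceosomal RNA, by 1.54 ± 0.28 from 2.12 to 6.29 CPM (adjusted p = 0.0491, same test). It lies below the 10 CPM of the naming rule and was chosen after its value was seen. Its call was lost in 5 of the 6 fits without 1 library, with DESeq2's size factors and with all 18 libraries in the fit. U1 reads can be divided among near-identical copies. These 3 calls came from 1206 tested features, of which 179 had an unadjusted p under 0.05 and 18.4% had no overlap between the groups' libraries, where chance gives 10%.

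Of the 6 tested members of the miR-10 and miR-100 family 2 fell and 4 were not called, and 5 fell when adjusted over the list alone. The family's median was -1.22, and limma's camera test gave an adjusted p of 0.000814, with adjusted p = 0.433 with an estimated correlation. The paralogous cluster on chromosome 19 had values of -1.27 ± 0.30 for miR-99b-5p (52195871 to 52195892), -1.42 ± 0.30 for let-7e-5p (52196046 to 52196067) and -1.16 ± 0.26 for miR-125a-5p (52196521 to 52196544), with adjusted p of 0.0639, 0.0584 and 0.0584 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; miR-99b-5p and let-7e-5p were chosen after their values were seen. Among the 5 members of the miR-200 family, which maintains epithelial identity, none was called, 4 fell when adjusted over the list alone, and the median was -0.67. Camera gave an adjusted p of 0.0309, and adjusted p = 0.433 with an estimated correlation. miR-200a-3p and miR-429 each had a value of -0.67 (SE 0.15 and 0.17). The 3 members of the miR-29 family, repressors of collagen messages, were each below the control level and none was called, with 3 when adjusted over the list alone (median -0.51, camera adjusted p = 0.127). The other lists had camera adjusted p of 0.127 or more, and 0 of the 9 let-7 members were called.

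The METTL3 shRNA and control cell libraries passed the check of pairing by replicate number, which the labels do not state. With the replicate number as a block over all cell libraries 9 features were called in place of 3. That block also covered the ALKBH5 shRNA cell libraries, which did not pass the check. The added ones were miR-99b-5p (-1.36 ± 0.24, adjusted p = 0.0287), let-7e-5p (-1.48 ± 0.27, 0.031), miR-125a-5p (-1.20 ± 0.20, 0.0285), miR-4521 (-1.17 ± 0.20, 0.0285), all lower, and the U1 copies RNVU1-1 and RNU1-117P, both higher, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Under the block 1 list kept a camera call in place of 2. With library sizes and scaling taken from miRNA counts alone, which moved the miRNA fold changes by a median of 0.13, 12 miRNAs fell and 0 rose. DESeq2 called 26 features, of which 4 rose and 22 fell. Leaving out control cell replicate 1, or METTL3 shRNA cell replicate 3, gave 0 calls by edgeR, with miR-100-5p between -1.92 and -1.66 and miR-125b-5p between -2.05 and -1.61 over the left-out libraries. The call of miR-125b-5p was also lost without METTL3 shRNA cell replicate 2.

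**Figure D2:**
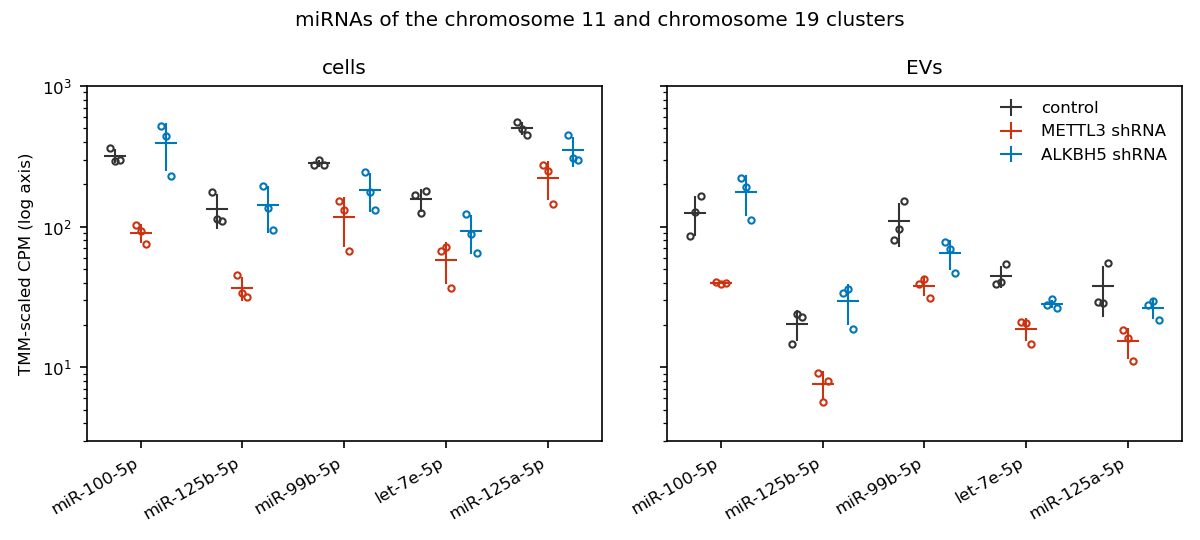
Points give the TMM-scaled CPM (log axis) of 5 miRNAs in each library, from cells (left panel) and EVs (right panel), of the control, METTL3 shRNA and ALKBH5 shRNA lines; dashes and bars give the mean and SD of 3 libraries. miR-100-5p lay at 90.6 ± 13.9 CPM in METTL3 shRNA cells against 318 ± 36.1 in control cells and 395 ± 148 in ALKBH5 shRNA cells, and at 39.7 ± 0.338, 126 ± 40.6 and 175 ± 57.1 CPM in the EVs of those lines.

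The second comparison asks what loss of the m6A eraser changed inside cells. ALKBH5 shRNA cells had higher RMRP and 2 called snoRNAs of 241 tested. RMRP (ENSG00000269900; chromosome 9, 35657748 to 35658015), the RNA component of the RNase MRP complex that processes pre-rRNA, rose by 0.95 ± 0.18 on the log2 scale, from 1067 ± 24.2 to 2060 ± 283 CPM (n = 3 per group). SNORD123 (ENSG00000239112; chromosome 5, 9548948 to 9549017), a snoRNA of the box C/D class whose members guide ribose methylation, rose by 0.99 ± 0.18, from 179 ± 8.06 to 355 ± 15.8 CPM, and SNORD63 (ENSG00000222937; chromosome 5, 137894659 to 137894728) rose by 1.22 ± 0.22, from 8.08 to 18.8 CPM. RNU2-23P (ENSG00000222477), a copy of the U2 spliceosomal RNA that lies under the naming rule's 10 CPM and was chosen after its value was seen, rose by 1.69 ± 0.32, from 2.17 to 7.02 CPM. All 4 had an adjusted p of 0.0483 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0 features fell. At an unadjusted p under 0.05 there were 182 features, 132 higher and 50 lower (104 features without ALKBH5 shRNA cell replicate 2 and 116 without control cell replicate 1). Among the 241 tested snoRNAs 64 were higher and 1 lower, and among the 543 miRNAs 2 were higher and 47 lower. The snoRNAs SNORD42A (+1.52 ± 0.34), SNORD43 (+1.28 ± 0.30; ENSG00000263764) and MIR3607 (+1.39 ± 0.32), chosen after their values were seen, were not called (adjusted p = 0.0940, 0.0953 and 0.0953).

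The miRNAs that were lower in METTL3 shRNA cells were not called in ALKBH5 shRNA cells: miR-100-5p had +0.31 ± 0.27 and miR-125b-5p +0.08 ± 0.29, while miR-99b-5p had -0.62 ± 0.30 and let-7e-5p -0.76 ± 0.29; all but miR-100-5p were chosen after their values were seen. No list with at least 3 tested members passed camera here; the smallest adjusted p, 0.0548, was that of the miR-320 family (adjusted p = 0.73 with an estimated correlation). The 4 calls were lost with DESeq2's size factors (0 calls), with all 18 libraries in the fit (0) and without any single library of the groups (0, or 1 other feature without ALKBH5 shRNA cell replicate 3). Over the left-out libraries the fold changes kept their sign, at 0.80 to 1.04 for RMRP, 0.90 to 1.007 for SNORD123, 1.12 to 1.29 for SNORD63 and 1.35 to 1.96 for RNU2-23P. The DESeq2 test gave 29 calls, 20 higher and 9 lower. Scaling on miRNA counts alone moved the miRNA fold changes by a median of 0.19. The miRNA median went from -0.22 to -0.029, and 293 of 532 miRNAs lay below 0 in place of 412 of 543. The lower level of most miRNAs in these cells thus depended on the scaling.

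Comparing the 2 knockdown cell lines directly sets opposite manipulations of m6A against each other. METTL3 shRNA cells had lower miR-100-5p (by 2.12 ± 0.28 on the log2 scale, 90.6 ± 13.9 against 395 ± 148 CPM, adjusted p = 0.00541 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and lower miR-125b-5p (-1.94 ± 0.30, adjusted p = 0.00838, same test). They also had lower miR-194-5p, an intestinal epithelial miRNA (-0.94 ± 0.19; chromosome 1, 220291548 to 220291569; 2369 ± 473 against 4536 ± 149.8 CPM), and lower RMRP (-1.06 ± 0.18). snoRNAs made up most of the difference: 16 of 241 were lower and 0 higher, among them MIR3607 (-1.93 ± 0.32; ENSG00000199262, chromosome 5, 85916323 to 85916385), SNORD43 (-1.83 ± 0.30; chromosome 22, 39715055 to 39715118), SNORD42A (-1.75 ± 0.34; ENSG00000238649, chromosome 17, 27050447 to 27050510) and SNORD123 (-1.18 ± 0.18), the last chosen after its value was seen. miR-874-3p (+1.61 ± 0.36) and miR-512-3p (+1.57 ± 0.36), both under 10 CPM and chosen after their values were seen, were the only features that were higher. miR-675-5p, also under 10 CPM and chosen after its value was seen, was lower (-1.37 ± 0.30, 1.60 against 4.15 CPM). It had an adjusted p of 0.0401 by edgeR's quasi-likelihood test, and its call was lost in each fit without 1 library. In all, 23 of 1206 features were called, 2 higher and 21 lower.

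In the miR-10 and miR-100 family 2 of 6 tested members fell, 3 when adjusted over the list alone, with a camera adjusted p of 2.69e-05 and adjusted p = 0.40 with an estimated correlation. In the intestinal miR-192 and miR-194 list 1 of 3 members fell, 2 when adjusted over the list alone, with adjusted p = 0.0125 by camera and adjusted p = 0.40 with an estimated correlation. The number of calls rested on single libraries, at 6 without METTL3 shRNA cell replicate 1, 6 without METTL3 shRNA cell replicate 2, 35 without METTL3 shRNA cell replicate 3, 3 without ALKBH5 shRNA cell replicate 2 and 7 without ALKBH5 shRNA cell replicate 3; DESeq2 called 40. Lower snoRNAs made up 3, 4 and 29 of the calls without METTL3 shRNA cell replicate 1, 2 and 3. They made up 17, 1 and 3 without ALKBH5 shRNA cell replicate 1, 2 and 3. Their majority among the calls was therefore not kept in each of these fits. With miRNA features alone 4 fell and 0 rose.

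In EVs, METTL3 shRNA against control gave 0 calls among 1697 features by edgeR, 71 at an unadjusted p under 0.05 (23 higher, 48 lower) and 13 by DESeq2 (1 higher, 12 lower). The unadjusted count was 219 without control EV replicate 3 and 109 without control EV replicate 2. The smallest adjusted p, 0.0616, was shared by miR-100-5p (-1.66 ± 0.30; 39.7 ± 0.338 against 126 ± 40.6 CPM, n = 3), miR-99b-5p (-1.54 ± 0.30) and miR-675-3p (-2.49 ± 0.48), which is processed from the H19 transcript, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. miR-125b-5p had -1.43 ± 0.33, let-7e-5p -1.24 ± 0.26, miR-193b-3p -1.22 ± 0.24 (chromosome 16, 14397874 to 14397895) and the selenocysteine tRNA -1.43 ± 0.35. Of these, all but miR-100-5p and miR-99b-5p were chosen after their values were seen. Of the 6 members of the miR-10 and miR-100 family 0 were called, 4 fell when adjusted over the list alone, and camera gave an adjusted p of 0.000943 (adjusted p = 0.952 with an estimated correlation). The miR-34 and miR-449a family, whose miR-34a is a p53 target, had a median of +0.86 with 0 of 4 members called and a camera adjusted p of 0.0121 (adjusted p = 0.952 with an estimated correlation). Without control EV replicate 3, the library with 37.0% 28S rRNA, 10 features were called: miR-100-5p (-1.40 ± 0.28), miR-99b-5p (-1.21 ± 0.26), miR-193b-3p, miR-146a-5p, miR-675-3p, miR-675-5p, miR-125a-3p and the selenocysteine tRNA (-1.71 ± 0.28) were lower, and SNORA38 and 28S rRNA (+2.42 ± 0.48) were higher. With all 18 libraries in the fit 7 features were called, all lower. The share of features with no overlap between the groups, 8.66%, was below the 10% of chance, and scaling on miRNA counts alone moved the miRNA fold changes by a median of 0.17.

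ALKBH5 shRNA EVs against control EVs also gave 0 calls by edgeR, with 69 features at an unadjusted p under 0.05 (38 higher, 31 lower) and 4 by DESeq2. The unadjusted count was 144 and 140 without control EV replicate 2 or replicate 3, and 41 and 43 without ALKBH5 shRNA EV replicate 1 or replicate 3. The snoRNA SNORD50 (ENSG00000202335; chromosome 12, 110934157 to 110934226) had the smallest adjusted p, 0.0719 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at +2.71 ± 0.48 and 15.8 ± 12.2 against 2.38 ± 0.284 CPM, and miR-515-5p, from the primate-specific miRNA cluster on chromosome 19, had -2.62 ± 0.54 (adjusted p = 0.188, same test); both were chosen after their values were seen. The level of miR-515-5p was 0.352 ± 0.138 CPM in ALKBH5 shRNA EVs against 2.15 ± 0.910 CPM in control EVs. The former is close to the 0.295 to 0.337 CPM that a count of 0 allows in EVs. Leaving out ALKBH5 shRNA EV replicate 2 gave 1 call, SNORD50, and leaving out control EV replicate 3 gave 1 call, miR-515-5p. With all 18 libraries in the fit 4 features were called. miR-100-5p had +0.48 ± 0.30 and miR-125b-5p, chosen after its value was seen, +0.54 ± 0.32. No list passed camera, with 0.216 as the smallest adjusted p.

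Between the EVs of the knockdown lines 4 of 1697 features were called, and all 4 were lower in METTL3 shRNA EVs. They were miR-100-5p (-2.14 ± 0.31; 39.7 ± 0.338 against 175 ± 57.1 CPM; adjusted p = 0.00755 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), miR-125b-5p (-1.97 ± 0.34; 7.57 ± 1.75 against 29.6 ± 9.53 CPM), and both arms of the H19 hairpin, miR-675-3p (-3.10 ± 0.47; chromosome 11, 2017998 to 2018017) and miR-675-5p (-2.03 ± 0.35; 2018030 to 2018052), which lie under 10 CPM and were chosen after their values were seen. miR-675-3p lay at 0.609 ± 0.131 CPM in METTL3 shRNA EVs against 5.35 ± 2.34 CPM in ALKBH5 shRNA EVs. The former is not far above the 0.295 to 0.337 CPM that a count of 0 allows in EVs. miR-675-5p lay at 1.53 against 6.26 CPM, and it was also called lower between the cells of these lines. In the miR-10 and miR-100 family 2 of 6 members fell and 4 when adjusted over the list alone (camera adjusted p = 0.000522, and adjusted p = 0.575 with an estimated correlation). The miR-181 family had 0 of 4 members called and a median of +0.30 (camera adjusted p = 0.0188; adjusted p = 0.575 with an estimated correlation). Of 272 Y RNA features 66 had an unadjusted p under 0.05, each with the higher level in METTL3 shRNA EVs, and 0 were called. Of all features 126 had such a p, but 48 without METTL3 shRNA EV replicate 2, 66 and 55 without ALKBH5 shRNA EV replicate 1 or replicate 3, and 269 without control EV replicate 3. The calls fell to 0 without METTL3 shRNA EV replicate 2 or replicate 3 and to 2 without ALKBH5 shRNA EV replicate 1 or replicate 2, and came to 7 without control EV replicate 3. Over the left-out libraries miR-100-5p had -2.38 to -1.93, miR-125b-5p -2.22 to -1.79, miR-675-3p -3.34 to -2.74 and miR-675-5p -2.22 to -1.89. With miRNA features alone, which moved the miRNA fold changes by a median of 0.17, 3 rose and 4 fell.

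The comparison of EVs with their parent cells asks which small RNAs were higher or lower in EVs than in cells. The medium held bovine serum, and serum RNA of the same sequence would be counted too. A higher level in EVs therefore need not come from export by the cells. In the control line 811 features were higher and 561 lower in EVs among 1841 tested, in the METTL3 shRNA line 767 and 596, and in the ALKBH5 shRNA line 790 and 502, by edgeR's quasi-likelihood test. In all 3 lines the same 719 features were higher and the same 440 lower, and 0 were called in opposite directions. The log2 ratios of pairs of lines correlated at 0.955 to 0.963 (Pearson's r across features, which are not independent replicates). EVs were richer in tRNA, Y RNA and lincRNA features and poorer in snoRNA and in most mitochondrial tRNAs. Of 333 lincRNA features 277 rose and 25 fell in the control line (median +5.36). Of 143 snRNA features 84 rose and 13 fell (median +1.98). Within cells 45 lincRNA features passed the filter and within EVs 365, so many entered this test through their level in EVs. The same limit holds for Y RNA (167 in cells and 272 in EVs), snRNA (76 and 130) and rRNA (46 and 71). For tRNA the numbers were 50 and 52, and for snoRNA, with more in cells, 241 and 212. In the control line 46 of 52 tRNA features rose and 0 fell (median +2.44), 266 of 268 Y RNA features rose and 1 fell (median +2.59), 46 of 70 rRNA features rose and 0 fell (median +1.66), 212 of 265 snoRNAs fell and 10 rose (median -2.43), and 14 of 22 mitochondrial tRNAs fell and 2 rose (median -1.75). These medians had the same sign in the other lines and with DESeq2's size factors. That scaling moved the fold changes of all features by a median of 0.14 in the control line and 0.26 in the METTL3 shRNA line, and scaling on miRNA counts alone, in which only miRNAs were tested, moved the miRNA fold changes by a median of 0.70, 0.71 and 0.41 in the control, METTL3 and ALKBH5 shRNA lines.

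**Figure D3:**
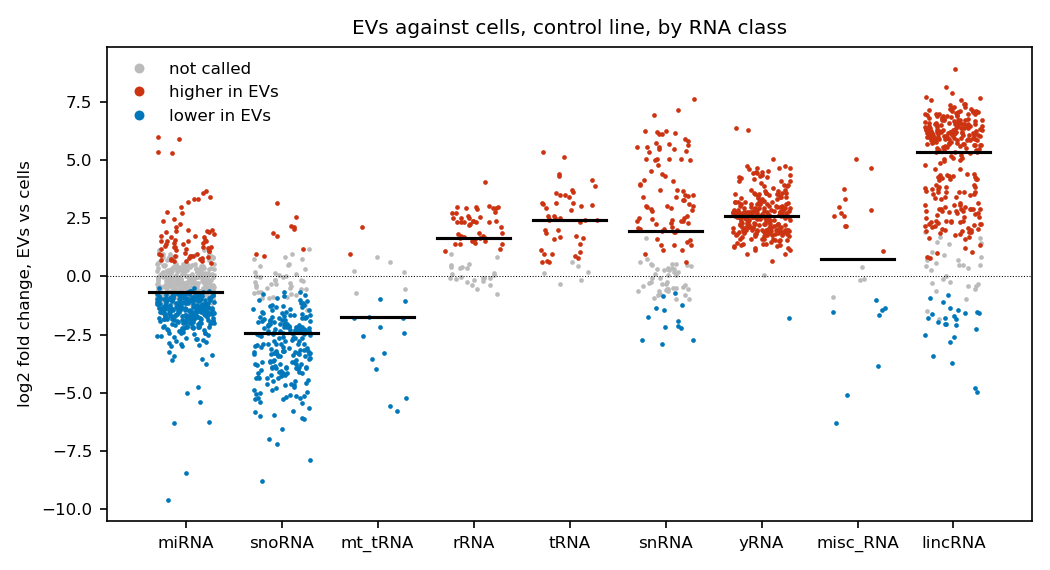
Each point is 1 tested feature of the control line, placed by its log2 fold change of EVs against cells (3 libraries each) within its RNA class; colours mark features called higher or lower by edgeR, and black lines the class medians. Most Y RNAs (median +2.59) and tRNAs (median +2.44) lay above 0 and most snoRNAs (median -2.43) below, as they also did with DESeq2's size factors.

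The glycine tRNA tRNA-Gly-GCC, the most abundant feature of 6 EV libraries, rose by 4.13 ± 0.28 in control EVs, to 252557 ± 39742 CPM from 14382 ± 2592 CPM (n = 3 each), by 3.91 ± 0.27 in METTL3 shRNA EVs and by 3.72 ± 0.27 in ALKBH5 shRNA EVs. tRNA-Glu-CTC rose by 4.42 ± 0.34, 3.47 ± 0.32 and 3.37 ± 0.32 in the same order. tRNA-Gly-GCC was chosen after its value was seen in the control line, and tRNA features merge several genes (10 for tRNA-Glu-CTC), so the gene of origin is not resolved. The vault RNA VTRNA1-1 (ENSG00000199990; chromosome 5, 140090860 to 140090958), part of the vault particle, rose by 2.97 ± 0.32, 2.84 and 3.16. RMRP rose by 2.80 ± 0.33 in the control line, and by 2.05 ± 0.32 in the METTL3 shRNA line. Among spliceosomal RNAs the U4 gene RNU4-2 (ENSG00000202538; chromosome 12, 120729566 to 120729706) fell by 2.72 ± 0.28, 2.88 and 3.20 and the U5 gene RNU5E-1 had -2.73 ± 0.35, -3.12 and -3.52. The U2 copy RNU2-29P rose by 6.18 ± 0.43, 6.99 and 6.26. Among snoRNAs SNORD19B (ENSG00000252787; chromosome 3, 52722898 to 52722977) fell by 8.80 ± 0.47 in the control line, from 1299.8 ± 295 to 3.0005 ± 1.62 CPM. SNORD89 rose by 1.86 ± 0.36. The mitochondrial tRNAs for isoleucine and aspartate fell by 5.80 ± 0.36 and 5.56 ± 0.38, whereas that for methionine rose by 2.12 ± 0.32. RN7SK, which holds back the elongation factor P-TEFb, fell by 1.65 ± 0.38. AC073283.4 (ENSG00000234690; chromosome 2, 47419544 to 47572213), a long non-coding RNA, rose by 4.79 ± 0.36, 4.05 and 4.43. Each of these changes in the named RNAs had an adjusted p under the threshold by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

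Among miRNAs 68 rose and 288 fell in control EVs, 39 and 309 in METTL3 shRNA EVs and 65 and 229 in ALKBH5 shRNA EVs, relative to all RNA. Relative to miRNAs alone the split was 161 and 134, 123 and 120, and 117 and 132. Among the miRNAs that rose was miR-1246 (chromosome 2, 177465752 to 177465770), at +5.92 ± 0.39, +6.61 ± 0.40 and +6.51 ± 0.40 in the control, METTL3 and ALKBH5 shRNA lines; its sequence also lies within U2 spliceosomal RNA. miR-3182 had +5.34 ± 0.55, +5.95 and +6.65, miR-320d +2.45 ± 0.27, +2.46 and +2.18, and miR-92b-3p +1.58 ± 0.23 in the control line and +1.65 in the ALKBH5 shRNA line, and it also rose in the METTL3 shRNA line. Among the miRNAs that fell were miR-12135 (-9.60 ± 0.51, -8.45 and -8.37; chromosome 15, 73592303 to 73592320), miR-4521 (-6.31 ± 0.44, -5.87 and -5.10), miR-1275 (-5.41 ± 0.45, -5.54 and -4.51) and miR-4517 (-5.00 ± 0.36, -5.55 and -5.06). miR-7974 also fell in the METTL3 shRNA line, from 12.2 ± 6.56 CPM to 0.0871 CPM, where too few counts were left for a fold. miR-125a-5p fell by 3.37 ± 0.33, 3.54 and 3.36. miR-21-5p fell by 1.84 ± 0.30 in the control line, and miR-92a-3p rose by 0.58 ± 0.21.

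By family, the tumour-suppressive let-7 miRNAs were lower in EVs: of 9 members 9, 9 and 8 fell in the control, METTL3 and ALKBH5 shRNA lines, and 9 in each when adjusted over the list alone, with medians of -1.83, -1.40 and -1.51. Camera gave adjusted p of 0.0054, 0.0156 and 0.00554, and adjusted p = 0.476, 0.696 and 0.484 with an estimated correlation. With scaling on miRNAs alone the medians were -1.05, -0.67 and -1.08. In the miR-320 family 3 of 5 members rose in each line, miR-320b (+1.27, +0.98 and +0.93), miR-320c (+1.51, +1.31 and +1.19) and miR-320d, and 3 when adjusted over the list alone. miR-320a-3p, the most abundant member, had +0.37 ± 0.21, -0.15 ± 0.21 and +0.10 ± 0.21 and was not called. Camera gave the family adjusted p of 5.53e-05, 0.000118 and 0.00554, and adjusted p = 0.27, 0.323 and 0.484 with an estimated correlation. All 4 members of the miR-181 family fell in each line (4 when adjusted over the list alone), which passed camera in the ALKBH5 shRNA line (adjusted p = 0.0194; adjusted p = 0.484 with an estimated correlation) and not in the control and METTL3 shRNA lines (0.088 and 0.102).

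None of the other lists passed camera in any line, and the miR-26 family had too few tested members for camera. In the control line, the miR-200 family had 5 of 5 members lower, miR-10 and miR-100 6 of 6, miR-34 and miR-449a 4 of 4, miR-192 and miR-194 3 of 3, miR-15 and miR-16 6 of 6, miR-148 and miR-152-3p 3 of 3, miR-26 2 of 2, miR-30 4 of 5 and miR-23, miR-24 and miR-27 4 of 5. The same number was called when adjusted over each of these lists alone. The miR-29 family had 1 of 3 members lower (3 when adjusted over the list alone), the miR-17-92 clusters had 1 of 11 members higher and 8 lower (9 when adjusted over the list alone), miR-221 and miR-222-3p had 1 of 4 higher and 2 lower (3), the miRNAs raised in colorectal cancer had 1 of 9 higher and 6 lower (7), and the mirtrons, which bypass Drosha, had 3 of 5 higher and 1 lower (4). Relative to miRNAs alone the control median of miR-221 and miR-222-3p was +0.30 (-0.41 relative to all RNA), and the fallen members came to 1 in miR-17-92, 2 in miR-10 and miR-100 and 2 in miR-15 and miR-16. Of 6 blood, serum and liver miRNAs 5 were called in the control line, also 5 when adjusted over the list alone. The erythroid miR-451a rose by 2.78 ± 0.73, to 2.03 CPM in EVs, and the liver miR-122-5p by 3.33 ± 0.86, to 1.78 CPM, and both also rose in the METTL3 shRNA EVs (3.06 and 2.19) and the ALKBH5 shRNA EVs (3.51 and 2.51); this pair was chosen after the values were seen. The endothelial miR-126-3p fell by 2.16 ± 0.32 and the haematopoietic miR-142-3p by 2.62 ± 0.39 in the control line. The cells were grown in medium with bovine serum, and a serum miRNA of the same sequence would be counted as the human one, so the source of miR-451a and miR-122-5p in EVs is not resolved. Of 4 mesenchymal and muscle miRNAs 1 rose in the control line, miR-145-5p (+2.97 ± 1.32, adjusted p = 0.0456 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), at 0.486 ± 0.600 CPM, and 0 when adjusted over the list alone.

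Whether knockdown changed export was tested as the difference between the EV to cell ratio of each knockdown line and that of the control line. For METTL3 shRNA 0 of 1841 features were called by edgeR, with 101 at an unadjusted p under 0.05 (30 higher, 71 lower), 0 by DESeq2 and 0.607 as the smallest adjusted p. The unadjusted count was 184 without control EV replicate 2. miR-100-5p had a change of +0.13 ± 0.44 and miR-125b-5p, chosen after its value was seen, of +0.41 ± 0.45, both not called. They were lower in METTL3 shRNA cells and had values of -1.66 and -1.43 in the EVs. For ALKBH5 shRNA 0 features were called by edgeR, with 123 at an unadjusted p under 0.05 (29 higher, 94 lower) and 1 by DESeq2. The unadjusted count was 277 without control EV replicate 2, 67 without ALKBH5 shRNA cell replicate 2 and 75 without control cell replicate 1. The smallest adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0940, that of SNORD50 (+2.999 ± 0.61), which was called (1 feature) without ALKBH5 shRNA EV replicate 2. In the miR-320 family 0 of 5 members were called and 0 when adjusted over the list alone. All 5 had a value below 0, with a median of -0.32, and camera gave an adjusted p of 0.00543 (adjusted p = 0.883 with an estimated correlation). DESeq2's size factors moved the values of all features by a median of 0.12 for METTL3 shRNA and of -0.15 for ALKBH5 shRNA, and miRNA-only scaling moved the miRNA values by a median of -0.29 for ALKBH5 shRNA; the miR-320 median stayed below 0 in both. With simulated data of this size, the test for the METTL3 shRNA change recovered 52% of 4-fold and 1% of 2-fold changes.

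Because METTL3 and ALKBH5 act on adenosine in the DRACH motif (D is A, G or U, R is A or G, H is A, C or U), the miRNAs whose mature sequence holds it were compared with the others. In METTL3 shRNA cells 2 of the miRNAs with the motif fell and 0 rose, and 14 were called when adjusted over the list alone. Their median was -0.18, and that of the other 391 tested miRNAs -0.0867. Camera gave an adjusted p of 0.513 for this comparison, and 0.513 to 0.967 over the 11 comparisons. In ALKBH5 shRNA cells 0 of them were called, with a median of -0.24.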

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

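The tests of read sharing, motif, hairpin, GC content of 1 EV library, cell RNA, rRNA share and RNA fragments were chosen only after the result was seen; those of the single METTL3 shRNA line, of GC content in EVs against cells and of other splits were planned.

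The miR-320 family, whose hairpins can be made without Drosha, met the test of a difference between lines. Its EV to cell ratio was lower in the ALKBH5 shRNA line than in the control line, with a camera adjusted p of 0.00543, a median of -0.32 and a value below 0 for 5 of 5 members, 0 of them called by edgeR. With an estimated correlation the adjusted p was 0.883. The median was -0.46 with DESeq2's size factors, -0.65 with miRNA features alone and -0.25 without control EV replicate 3. Within compartments the ALKBH5 shRNA line had medians of -0.13 in EVs and +0.22 in cells against control. No explanation of it was tested.

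The first pattern weighed is the lower miR-100-5p, miR-125b-5p and miR-99b cluster in METTL3 shRNA cells. Reads moved between near-identical family members would leave the opposite arms of the hairpins near 0. However, 4 such arms, 1 of miR-125b and 3 of the miR-99b cluster and none called by itself, had a median of -1.53. The opposite arm of miR-100-5p was not tested. Its sum with miR-99a-5p and miR-99b-5p had -1.57 ± 0.26, which alone does not decide, because miR-99b-5p was itself lower. In METTL3 shRNA cell replicate 1, the highest in both, miR-100-5p lay at 103 CPM and miR-99b-5p at 153 CPM. Together these lay below the lowest control level of miR-100-5p alone (295 CPM), and miR-99a-5p averaged 5.22 counts. These values argue against an unchanged miR-100-5p whose reads were counted to these arms. The m6A motif in the mature miRNA alone would lower all miRNAs with the motif, yet their median lay only -0.0934 from the others (95% interval -0.189 to 0.000191), and let-7e-5p, without the motif, had -1.42 ± 0.30. That interval came from 10000 resamplings of the miRNAs as if independent. It does not measure the spread between libraries. A hairpin in the line, whatever its target, would lower miR-100-5p and miR-125b-5p in ALKBH5 shRNA cells too, where their mean was 0.197. This argues against a hairpin effect on these miRNAs unless ALKBH5 loss raised them there, which was not tested. For the miR-99b cluster, with a median of -0.66 there (median SE 0.30), a hairpin effect cannot be told apart from METTL3 loss. With 1 METTL3 shRNA line a difference between stable lines other than METTL3 loss cannot be told apart from METTL3 loss.

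The second pattern is control EV replicate 3, which lay further from the other libraries of its group (root mean square log2 distance 1.10) than the remaining EV libraries from theirs. Its deviation rose with the GC content of the miRNA (Spearman's rho 0.454), so loss of miRNAs low in G and C stays open, though trends of nearly that size ran the other way in control EV replicate 2 (-0.432, against a mean that holds replicate 3) and control cell replicate 3 (-0.41); control EV replicate 1 had -0.297, and the METTL3 and ALKBH5 shRNA EV libraries -0.21 to 0.238. RNA of cells in the preparation would bring snoRNA, and the library's snoRNA share was 0.209%, the lowest of the EV libraries. However, rRNA took 40.8% of its counts, which lowers the share of every other class. The snoRNA share therefore does not decide whether RNA of cells was present. A high share of rRNA fragments (40.8%) as the whole cause is opposed by the distance with rRNA features left out, which was still 1.08 against at most 0.686 in the other EV libraries. No biological explanation was tested.

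The third pattern is the set of 33 miRNAs that were higher in EVs than in cells in all 3 lines. If fragments of other small RNAs with exactly the miRNA's sequence were the cause, many of the 33 would lie inside such RNAs. Of the 33, 2 did (6.06%, 95% interval 0.743 to 20.2), miR-1246 in U2 RNA and miR-12136 in a mitochondrial serine tRNA. Of those that fell 0 did (Fisher's exact p = 0.0206). Only exact matches of the whole mature sequence were counted, so fragments that differ by a base or match in part stay open. 18S and 28S rRNA were not searched, so fragments of these stay open too. GC content of the miRNA correlated with the EV to cell ratio at rho 0.282, 0.106 and 0.205, between the bounds set beforehand, and its part cannot be told apart from selective export.

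With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split alone (1 of 10) gave as many calls for METTL3 shRNA against control cells (3, highest other 0), ALKBH5 shRNA against control cells (4 and 0), METTL3 against ALKBH5 shRNA cells (23 and 0) and EVs (4 and 0), and EVs against cells in the control (1372 and 0), METTL3 shRNA (1363 and 0) and ALKBH5 shRNA (1292 and 0) lines. A real count of 0 is met by every split, so for the following comparisons the splits decide nothing: 10 of 10 for METTL3 shRNA against control EVs (real 0, highest other 0; 71 features at an unadjusted p under 0.05 by edgeR, 13 by DESeq2) and 10 of 10 for ALKBH5 shRNA against control EVs (real 0, highest other 10; 69 unadjusted, 4 by DESeq2). The same holds for the changes of EVs against cells, with 100 of 100 drawn splits each (real 0 by edgeR; 101 and 123 unadjusted, 0 and 1 by DESeq2), with highest others of 23 for METTL3 shRNA and 38 for ALKBH5 shRNA. Without single libraries of the groups the unadjusted counts ran from 58 to 219, 41 to 144, 81 to 184 and 67 to 277 in the order given. The other splits with calls (1 of the EV comparison, 4 and 9 of the drawn ones) point to a structure among the libraries, whose cause was not tested.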

How the results depend on the processing

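The fits without control EV replicate 3 for comparisons in which it is in neither group, and the motif test without the miR-10 and miR-100 family, were chosen only after the result was seen. A count of called features or lists was scored the same if it stayed within a set factor of the planned count. A share was the same if it moved by no more than the larger SD of the groups. The only alternatives for shares left out 1 of 3 libraries, which cannot move a group's mean by more than its SD. Every share was thus bound to be scored the same, so the shares among the 443 values below say nothing about stability. Motif tests and named features were the same if called, or not called, in both. Of the counts, lists, shares and motif tests 443 values were the same, 33 weaker and 29 stronger. Of the values of named features 2524 were the same, 123 weaker and 69 stronger. While 0 called values turned direction, uncalled ones could change sign and count as the same. DESeq2's size factors gave 0 calls for ALKBH5 shRNA against control cells (4 by the planned test). DESeq2 gave 26 and 29 for METTL3 and ALKBH5 shRNA against control cells, 13 and 4 against control EVs, 40 for METTL3 against ALKBH5 shRNA cells and 1 for the ALKBH5 shRNA change of EVs against cells. Without a filter on low counts the same comparisons gave 73, 42, 8, 7, 62 and 6, METTL3 against ALKBH5 shRNA EVs 7, the METTL3 shRNA change 1 and 2136 for EVs vs cells, METTL3 shRNA. With miRNA features only, where fewer features are tested, METTL3 shRNA cells gave 12 calls, ALKBH5 shRNA cells 0 (none of the 4 planned calls there is a miRNA, so their loss was fixed beforehand), METTL3 against ALKBH5 shRNA 4 in cells and 7 in EVs, and EVs against cells 295, 243 and 249 in the control, METTL3 and ALKBH5 shRNA lines. The replicate block gave 9, 25 and 37 for METTL3 and ALKBH5 shRNA against control cells and against each other. Only the first of these comparisons passed the check of pairing. All 18 libraries in the fit gave 0 for ALKBH5 shRNA cells, and 7 and 4 for METTL3 and ALKBH5 shRNA against control EVs. Leaving out 1 library of the groups compared gave 0 to 4 for METTL3 shRNA against control cells, 0 to 1 for ALKBH5 shRNA, 0 to 10 and 0 to 1 for the same in EVs, 3 to 35 for METTL3 against ALKBH5 shRNA cells, 0 to 4 in EVs (7 without control EV replicate 3, in neither group), and 0 to 1 for the ALKBH5 shRNA change. Lists called by camera came to 0 with an estimated correlation in each comparison that had one, to 1 with miRNA features only in METTL3 and in ALKBH5 shRNA cells (2 and 0 by the planned test), and to 1 with the replicate block in METTL3 shRNA cells. Except where fewer features or libraries were tested, the cause was not tested. The depth of cell libraries limits a count of 0 to 0.356 to 1.014 CPM.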

Other observations

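The tests of miRNA genomic clusters were chosen only after the result was seen. Neighbouring miRNAs within 10000 bp were grouped into 35 clusters and tested with camera. The primate-specific cluster on chromosome 19 (54169946 to 54265632), active in placenta and silent in most adult tissues, had 12 of 12 tested members below 0 in ALKBH5 shRNA cells against control (median -1.08, adjusted p = 0.000608, and 0.890 with an estimated correlation) and 9 of 10 in EVs (median -1.16, adjusted p = 1.2e-08, and 0.283). In METTL3 against ALKBH5 shRNA EVs 10 of 10 were above 0 (median +1.27, adjusted p = 7.3e-15, and 0.0739). Levels were low: miR-512-3p lay at 4.34 against 1.09 CPM in these EVs. In cells miR-516b-5p lay at 1.62 CPM in the ALKBH5 shRNA line against 5.36 CPM in control. Both of these miRNAs have 2 locations in the genome. The miR-424 and miR-450b cluster on chromosome X (133674224 to 133680731), linked to cell-cycle control, had 7 of 8 members below 0 in METTL3 shRNA cells (median -0.83, adjusted p = 0.00175, and 0.358) and 8 of 8 in ALKBH5 shRNA cells (median -0.73, adjusted p = 0.000608, and 0.270), against the same control libraries. The miR-193b and miR-365a cluster on chromosome 16 (14397837 to 14403218) had 3 of 3 members below 0 in METTL3 shRNA EVs (median -1.22, adjusted p = 6.15e-05, and 0.283). None of these kept its call with an estimated correlation.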
